A study of Homo sapiens with 9 samples.

How the data were processed

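ATAC-seq libraries were made from H1 human embryonic stem cells with OCT4:RFP and SOX2:YFP reporters, 3 libraries in each of 3 groups: before and after loss of mesendoderm competence, and a mesendoderm-derived outgroup. Per the labels' protocols, ectoderm differentiation used 0.5 µM A83-01, and mesendoderm competence was tested with 3 ng/mL BMP4 and 100 ng/mL Activin A for 36 hours. The populations were sorted by flow cytometry, the competent cells from the highest 10 to 15% of the OCT4 to SOX2 ratio and the others from the lowest 10 to 15%. Part of each sort was kept for the competence test, and the tagmentation with Tn5 took 30 min at 37 °C. Because the groups were gated on OCT4 and SOX2 reporter levels, the comparison before against after is between sorted extremes of the reporter ratio. Nothing in the labels says whether replicates came from separate cultures.

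The authors deposited 2 lists of regions, called less and more accessible with loss of competence, as chromosome, start and end. Per the submitters' processing notes, the tools were Bowtie2 2.2.9, SAMtools 1.9, Picard 2.8.0, MACS2 2.1.1, DiffBind 2.12.0, R 3.6.1 and HOMER 4.9, with the build hg38; the role of each is not stated. The thresholds behind the calls, the groups that entered them, the use made of the outgroup and any shift of reads for the Tn5 cut site are not given in the sources used here. Reads per library, and accessible regions that did not change, are not used here, so library depth, replicate spread and the size of each change could not be assessed. All 2306 regions were 500 bp wide, with 0 duplicates. With a common width, a region's midpoint was used as its position; coordinates are printed 1-based.

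Genes came from a RefSeq table for GRCh38.p14, the same assembly as hg38, with 59679 annotated genes, of which 20037 were protein-coding. The table gives gene start and end coordinates and neither strand nor transcripts, so the planned distance to a transcription start was replaced by distance to the gene body (0 inside) for the nearest gene and to either gene end for promoter-like position. Exon, intron and UTR classes could not be assigned. No genome sequence was used, so the planned tests of 53 motifs and of GC content were not run. The nearest gene of a region is a neighbour and need not be its target.

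The background was a grid of positions every 1000 bp between the first and last gene of each chromosome, leaving out gene-free stretches over 2 Mb. It covered 2881 Mb and left out 205.8 Mb, and 0 listed regions fell outside it. The accessible regions that could have been called would be the better background and were not analysed here. For each of 21 gene lists (635 distinct genes, 2 matched by an older symbol and 0 unmatched) and each direction, the number of regions nearest to a member was tested against the list's share of the grid with an exact binomial test, one-sided for more, with Benjamini-Hochberg adjustment over lists and directions and a threshold of 0.05. The lists covered pluripotency, mesendoderm and primitive streak, definitive endoderm, neural ectoderm, proneural and neuronal, surface ectoderm and placode, neural crest, trophoblast and extraembryonic, mesoderm derivatives, the TGF-beta, BMP, Wnt, FGF, Notch, Hippo and retinoic acid with Hedgehog pathways, HOX genes, the SOX, POU and ZIC families, cadherins and adhesion, chromatin modifiers and housekeeping genes. Several genes are in more than 1 list. The same test was run for each of 19965 genes with a territory on the grid, adjusted over all genes and over each list alone.

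Shares were compared between the lists of regions with Fisher's exact test, two-sided, and medians with permutation tests of 100000 resamples, two-sided, with bootstrap intervals of 2000 draws. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only; neighbouring regions are not independent, so they are too narrow where regions cluster. Clustering was compared with 1000 random placements on the same chromosomes and shared genes with 10000 placements. The lists, the kinds of test, 34 of 71 alternative values and the rule for named genes were chosen before the data were examined. Where these tests and alternatives used distance to a gene body or gene end, it replaced the planned distance to a transcription start. The list calls as tested therefore do not come from the planned distance. The other 37 alternative values, gene density, tests of single genes and comparisons with chromosome length were added later. The rule named up to 4 members per list and direction with the most regions, at most about 30 per direction, the 5 genes with the most regions in each direction, and POU5F1 and SOX2. Other genes are named where they make up a list's count.

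The list test was tested on simulated data. The nearest gene equalled that of a brute-force search at 400 of 400 positions, and 4 of 8400 list tests without enrichment were called. The simulated positions were drawn independently from the same grid as the background. These rates therefore do not cover regions that lie close together, as the more accessible ones do. A planted 2-fold neural ectoderm excess was called in 5.5% of simulated sets of the less accessible list's size and in 65.5% of the more accessible list's size. Alternatives covered windows of 500 bp and 2.5 kb, all annotated genes, 1 region per locus of 50 kb, a background matched on distance class, nearest genes within 100 kb, every gene within 50 kb, each gene once together with 1 region per locus, autosomes alone, and windows of 10 kb and 250 kb for clustering. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.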

Results

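Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in H1 human embryonic stem cells carrying fluorescent reporters on OCT4 (gene POU5F1) and SOX2. The cells were driven towards ectoderm with A83-01, an inhibitor of Activin and Nodal signalling, and sorted by the ratio of the reporters into a population still able to form mesendoderm (the common precursor of mesoderm and endoderm) and a population that had lost this competence. A mesendoderm-derived outgroup was profiled beside them, so that the 9 libraries formed 3 groups of 3. The design asks which regions open or close when mesendoderm competence is lost, and which of these changes are specific to the ectodermal fate. The values used here were the authors' deposited lists of regions called less or more accessible with loss of competence, in hg38 coordinates and with no value per region or per library. The spread between replicates, the depth per library and the size of each change are therefore not part of what follows, and intervals and p-values describe the regions of the lists as counted.

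Many more regions were listed as more accessible than as less accessible with loss of mesendoderm competence. Of 2306 listed regions, 2072 were more accessible and 234 less accessible, a ratio of 8.85. The less accessible share was 10.1% (95% exact binomial interval 8.94 to 11.5), and an exact two-sided binomial test against equal numbers gave a p-value whose log10 was -367. The test treats regions as independent. Neighbouring regions are not, and neither are regions called from the same libraries. The thresholds and groups behind the calls are not given here. The ratio therefore describes the lists and need not give the balance of changes in the cells. Every region was 500 bp wide, so the lists covered 1036 kb and 117 kb. The less accessible regions lay nearest to 226 protein-coding genes and the more accessible regions to 1609.

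Single less accessible regions lay at or near several genes of the fixed lists, none of which passed as a list. A region (chromosome 3, 46574272 to 46574771) overlapped the start coordinate of CRIPTO, formerly TDGF1, the co-receptor through which Nodal signals. Another lay inside CLDN7, a tight junction claudin (chromosome 17, 7262603 to 7263102), 1 lay 11.2 kb from APLNR, the apelin receptor used as a mesendoderm marker (chromosome 11, 57222163 to 57222662), and 1 lay 220 kb from ZFP42, the pluripotency marker REX1 (chromosome 4, 187775193 to 187775692). ETV5, an ETS factor downstream of FGF signalling, held 1 inside its body (chromosome 3, 186079843 to 186080342). Adjusted over all 19965 genes tested, none of the 226 had more less accessible regions than its share of the genome gives (exact binomial test, Benjamini-Hochberg adjustment), although 136 had an unadjusted p under 0.05, which a single region already gives a gene with little sequence around it. Adjusted over the list alone, CLDN7 passed within the cadherin and adhesion list (1 region against 0.000975 expected, exact adjusted p = 0.04), while CRIPTO reached 0.079 within the pluripotency list. The pass of CLDN7 rests on 1 region and on the little sequence nearest to that gene, and shows no gathering of regions there.

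When adjusted within a fixed list, 3 genes had more of the more accessible regions than their share of the genome gives. Of these, 1, NR2F1, also did when regions within 50 kb of each other counted as 1 locus. JARID2, a Polycomb cofactor, was nearest to 5 more accessible regions (0.598 expected), of which 2 lay inside the gene and 3 between 430 kb and 468 kb from it. DNMT3B, the de novo DNA methyltransferase, held 2 inside its body (chromosome 20, 32779582 to 32780081 and 32780681 to 32781180; 0.0439 expected). NR2F1, an orphan nuclear receptor of neural progenitors, was nearest to 5 (0.807 expected), at distances from 176 kb to 989 kb. Adjusted over the list alone, JARID2 (exact adjusted p = 0.014) and DNMT3B (0.017) passed within the pluripotency list and again within the chromatin modifier list (0.015 and 0.018), and NR2F1 (0.039) passed within the neural crest list but not within the neural ectoderm list, whose smallest value was 0.069. The test treats neighbouring regions as independent. With regions within 50 kb of each other counted as 1 locus, an alternative added after the data had been seen, JARID2 had 3 loci and DNMT3B 1 (exact adjusted p = 0.48 each within the pluripotency list), and neither passed, whereas NR2F1 kept 5 (0.029). The NR2F1 regions 283 kb and 337 kb from the gene lay little further apart than 50 kb, and wider loci were not tested. Over all genes tested the exact adjusted p was 0.64 for JARID2 and 0.93 for DNMT3B. In that adjustment 0 genes passed, with 339 at an unadjusted p under 0.05. Adjusted over the 635 genes of all lists jointly, 0 passed in either direction (smallest exact adjusted p = 0.62 for less and 0.25 for more accessible).

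**Figure D1:**
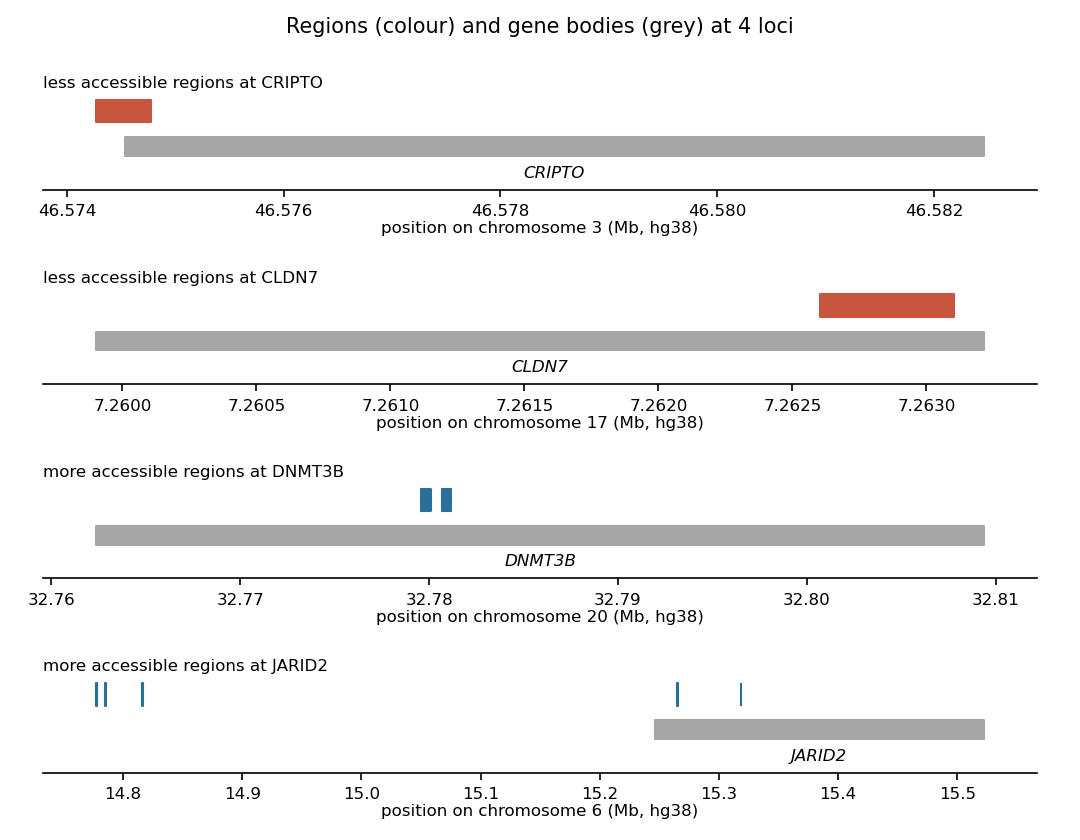
Maps of 4 loci with gene bodies in grey and listed regions in colour (red less accessible, blue more accessible), each on its own scale of position in Mb. The less accessible region at CRIPTO overlaps the gene's start coordinate, and 3 of the 5 more accessible regions nearest to JARID2 lie outside the gene.

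The genes with the most more accessible regions were DLG2, a synaptic scaffold, and SEMA6D, an axon guidance semaphorin, with 7 each. AUTS2, a neurodevelopmental gene, followed with 6. JARID2, NR2F1 and the cadherin CDH11 had 5 each. SEMA6D had 1.09 expected (exact unadjusted p = 0.00014, adjusted 0.39) and DLG2, which is a long gene, 1.62. In the less accessible list 8 genes were nearest to 2 regions each and none to more. By the rule for naming genes these were led by ASAP2, COL22A1, CSMD1, KCNJ16 and PDE4B.

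Neither reporter gene had a listed region within 500 kb. No region of either list had POU5F1 as its nearest protein-coding gene, and the closest less and more accessible regions lay 3538 kb and 564 kb away. SOX2 was the nearest gene of 1 more accessible region, 524 kb beyond its end (chromosome 3, 182238151 to 182238650). A less accessible region lay 571 kb from SOX2 (chromosome 3, 182284725 to 182285224), with ATP11B as its nearest gene.

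Whether developmental gene groups gathered more regions than the genome gives was tested with 21 lists of genes and exact one-sided binomial tests. Among more accessible regions, the trophoblast and extraembryonic list was nearest to 14, or 2.5 times its genome share (95% interval 1.37 to 4.19, exact adjusted p = 0.048), from ID2 and ISL1 with 3 each, GATA3 and IGFBP3 with 2 each, and BMP4, ELF5, TFAP2A and TFAP2C with 1 each. ISL1, ID2, BMP4 and GATA3 also act in neural or mesodermal tissue, and 3 of the 14 regions lay within 100 kb of the gene. The Wnt signalling list was nearest to 16 regions, 2.30 times its share (1.31 to 3.72, exact adjusted p = 0.048), 11 of them inside a gene. Its members were the Wnt antagonists and feedback inhibitors NKD1, SFRP1, ZNRF3, AXIN2 and DKK2, the effectors TCF7L1, TCF7L2 and CTNNB1, the receptor ROR1, and the ligands WNT1, WNT2B and WNT4. Both calls were marginal. Both used distance to the gene body in place of the planned distance to a transcription start. With the nearest gene end instead, an alternative chosen after seeing the data, the exact adjusted p was 0.061 for each list. Over 7 alternatives the adjusted p ran from 0.046 to 0.71 for the trophoblast list and from 0.0039 to 0.21 for the Wnt list, and counting each gene once together with 1 region per locus gave 0.17 and 0.089.

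The retinoic acid and Hedgehog, neural ectoderm and pluripotency lists stood next. The neural ectoderm list was nearest to 30 more accessible regions through 20 of its 47 members (1.64-fold, 1.11 to 2.33, exact adjusted p = 0.061), led by NR2F1 with 5 and by CDH2 (N-cadherin), GLI3, IRX3, OTX2, POU3F1 and SOX5 with 2 each. PAX6, LHX5 and SOX11 were among those with 1. The retinoic acid and Hedgehog list was nearest to 11 (2.55-fold, 1.27 to 4.55, exact adjusted p = 0.06), among them GLI3, HHIP and RARB with 2 each. The pluripotency list was nearest to 13 (2.17-fold, exact adjusted p = 0.061), of which JARID2 gave 5, DNMT3B and MYCN 2 each, and KLF4, KLF5, SALL1 and SOX2 1 each. BMP signalling had 19 (1.74-fold, exact adjusted p = 0.098), led by CRIM1 with 4, and the proneural list 10 (2.05-fold, adjusted p = 0.13), with ISL1, ATOH8, EBF2 and ELAVL4. None of these 5 lists passed the threshold as tested. With a background matched on distance to genes, the neural ectoderm, pluripotency and retinoic acid and Hedgehog lists passed as well, giving 5 lists, and with each gene counted once and 1 region kept per locus 0 passed. When every gene within 50 kb of a region was counted, the neural ectoderm list had 19 regions (3.13-fold, exact adjusted p = 0.00082) and passed with the Wnt list (2.63-fold, 0.0039), while the trophoblast list did not (1.39-fold, 0.71).

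Mesendoderm and endoderm genes showed no detectable excess of more accessible regions. The mesendoderm and primitive streak list was nearest to 5 more accessible regions (0.98-fold, 0.319 to 2.29), which lay nearest to APLNR, BMP4, GATA4, GSC and MSGN1, and to 1 less accessible region, nearest to APLNR. The definitive endoderm list was nearest to 5 more accessible regions (1.07-fold) and 0 less accessible ones. Among less accessible regions, counts of 1 and 0 are too small to show or exclude an excess. The folds among more accessible regions were 1.21 for surface ectoderm and placode (7 regions), 1.11 for neural crest (11), 1.33 for mesoderm derivatives (8), 1.38 for TGF-beta, Nodal and Activin signalling (7), 1.36 for FGF and ERK signalling (15), 1.37 for Notch (4), 1.05 for Hippo and TEAD (5), 1.26 for the SOX, POU and ZIC families (14), 0.98 for cadherins and adhesion (29) and 1.53 for chromatin modifiers (13), and none passed. HOX genes and the housekeeping comparison list were nearest to 0 regions in both directions, where 0.615 and 1.07 more accessible regions were expected.

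Among less accessible regions no list passed. The neural crest list came closest, with 5 regions nearest to NR2F2, PAX3, ZIC1, RARB and B3GAT1 (4.47-fold, 1.46 to 10.3, exact unadjusted p = 0.0057, adjusted p = 0.06), of which 2 lay within 100 kb of the gene. It passed with the matched background, where a simulated binomial test of 10000 draws gave an adjusted p of 0.05. That value was just under the threshold before rounding, so simulation error could decide it. The list also passed on autosomes alone (exact adjusted p = 0.049). It passed in none of the other 5 alternatives, among them nearest genes within 100 kb (2 regions, 0.41) and every gene within 50 kb (1 region, 0.7). The cadherin and adhesion list had 8 regions (2.40-fold, exact adjusted p = 0.1), among them CLDN7, CDH12, CNTNAP2 and NRXN3. FGF and ERK signalling had 4 (3.21-fold, exact adjusted p = 0.16), nearest to ETV5, FGF12, FGF14 and SPRY2, of which 2 lay within 100 kb of the gene. Neural ectoderm had 4, BMP signalling 3 (BMP5, FSTL4 and RGMB), pluripotency 2 (CRIPTO and ZFP42), TGF-beta, Nodal and Activin signalling 2 (CRIPTO and ACVR2A), the SOX, POU and ZIC families 2 (SOX5 and ZIC1), and Wnt (FZD1), proneural (MYT1L) and retinoic acid and Hedgehog (RARB) 1 each. Surface ectoderm, trophoblast, mesoderm derivatives, Notch, Hippo and chromatin modifiers had 0. In simulated lists of this size a 3-fold excess of the neural ectoderm list was called in 16.5% of sets and a 5-fold excess in 70.5%, against 100% for both at the size of the more accessible list, so a 3-fold excess of that list would mostly have been missed among less accessible regions. Other lists were not simulated, and the simulated positions were independent of each other.

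**Figure D2:**
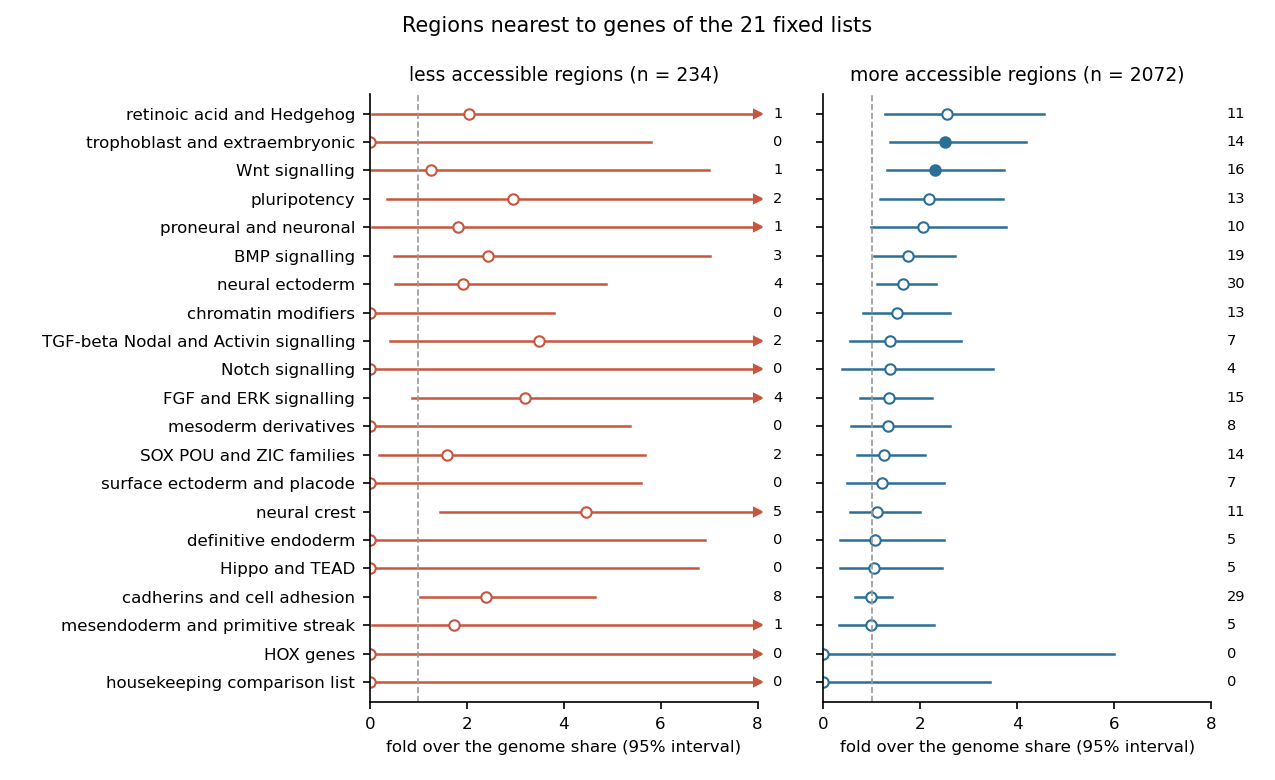
Fold of observed over expected regions for each of 21 gene lists (points; lines are 95% exact intervals, arrows mark intervals beyond the axis), in 234 less accessible regions on the left and 2072 more accessible regions on the right. Numbers at the right of each panel are regions, filled points have an adjusted p under 0.05, and the dashed line marks the genome share; the trophoblast and Wnt lists are the filled points.

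Setting the lists of regions against each other, no gene group differed past the threshold. The share of regions nearest to neural crest genes was 2.14% among less and 0.531% among more accessible regions (odds ratio 4.09, 1.10 to 12.9; Fisher's exact test, two-sided, p = 0.018, adjusted over 21 lists 0.37). For cadherins and adhesion it was 3.42% and 1.40% (odds ratio 2.49, 0.973 to 5.67, exact p = 0.047, adjusted 0.49). These were the 2 lists with an unadjusted p under 0.05, and 0 passed after adjustment.

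Regions of opposite direction shared no more genes than random placement gives, within the error. Of the 226 genes nearest to a less accessible region, 75 were also nearest to a more accessible one, among them APLNR, ACVR2A, CDH6, CDH8, NRXN3, RARB and SOX5. Random placement of the less accessible regions gave 69.4 on average (95% of placements 56 to 83, permutation p = 0.22). Fisher's exact test over genes gave p = 1.5e-27, but it treats a gene with a long territory like a short one. Within 50 kb of a more accessible region lay 14 less accessible regions (5.98%), where placements gave 16.4 (permutation p = 0.77). The 5 closest pairs lay 4.34 kb apart near KCNJ16, 6.56 kb in PDE4B, 6.78 kb near NDST4, 7.98 kb near TNFAIP8 and 8.93 kb near APLNR.

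Regions of either list lay mostly more than 1 kb from an end of a protein-coding gene. Transcript starts inside genes could not be placed. Within 1 kb of an end of a protein-coding gene lay 8 less accessible regions (3.42%, 1.49 to 6.63) and 57 more accessible regions (2.75%, 2.09 to 3.55), against 2.53% of the genome (odds ratio 1.25, 0.509 to 2.68, Fisher's exact test, two-sided, p = 0.53). Within 1 kb of an end of any annotated gene lay 11.1% of less and 7.67% of more accessible regions (odds ratio 1.50, 0.930 to 2.35, Fisher's exact test, two-sided, p = 0.075). The median distance to the nearest protein-coding gene end was 61.2 kb for less and 62.3 kb for more accessible regions. The difference was -1.03 kb (bootstrap 95% interval -17.4 to 17.9, permutation test, p = 0.9). Inside a protein-coding gene lay 97 less accessible regions (41.5%) and 993 more accessible regions (47.9%; odds ratio 0.769, 0.579 to 1.02, exact p = 0.062). Against 43.9% of the genome, the more accessible regions lay inside genes more often (1.09-fold, exact binomial test, p = 0.0002), while the less accessible ones did not pass (0.945-fold, p = 0.47).

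Less accessible regions lay more often in gene-poor surroundings than more accessible regions did. With no protein-coding gene within 500 kb were 27 of 234 less accessible regions (11.5%) and 110 of 2072 more accessible regions (5.31%), an odds ratio of 2.33 (1.43 to 3.67, Fisher's exact test, two-sided, p = 0.00061), where the genome had 8.40%. The less accessible interval (7.74 to 16.3) holds the genome's share, and the more accessible one (4.38 to 6.36) lies below it. With 20 or more genes, the less accessible interval (1.21 to 6.07) lies below the genome's 7.72%, and the more accessible one (6.21 to 8.49) holds it. More than 10 genes within 500 kb surrounded 12.8% of less and 22.5% of more accessible regions (odds ratio 0.506, 0.328 to 0.756, exact p = 0.00041). The mean number of genes was 5.38 and 7.50 (permutation test, two-sided, p = 0.00021), while the medians of 4 and 5 did not differ past the threshold (p = 0.18). These gene density results were added after the data had been seen. The tests of the classes and of the mean treat regions as independent and were not repeated with 1 region per locus.

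**Figure D3:**
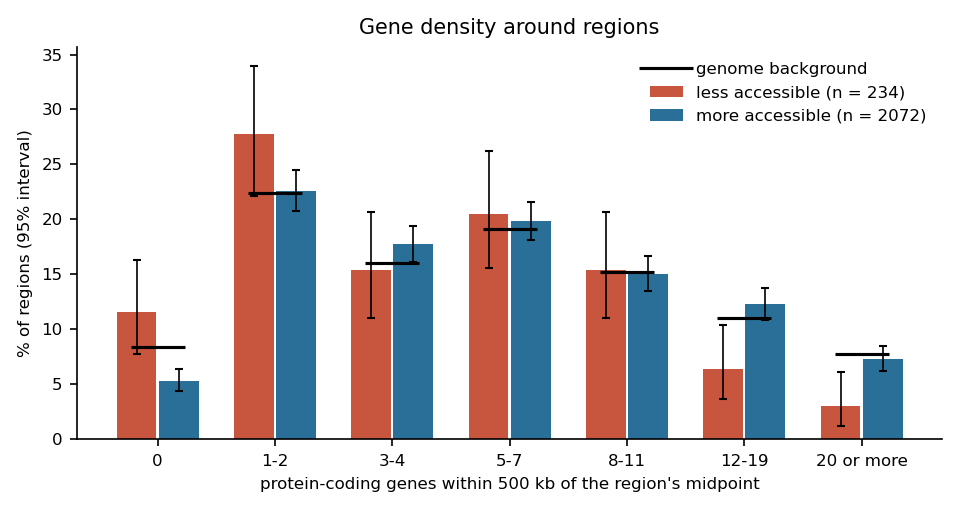
Percent of less (red, n = 234) and more accessible regions (blue, n = 2072) by the number of protein-coding genes within 500 kb, with 95% exact binomial intervals and the genome background as black dashes. The less accessible regions reach 11.5% in the class with 0 genes against 5.31% for the more accessible regions, and 2.99% against 7.29% in the class with 20 or more.

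More accessible regions lay in groups along the chromosomes. Another region of the same list lay within 50 kb for 265 of them (12.8%), where random placement on the same chromosomes gave 7.39% on average and 9.89% at most over 1000 placements (permutation p = 0.001, the smallest these placements can give). The densest runs, with steps of at most 100 kb between neighbours and 4 regions each, numbered 6 and lay near LAPTM5 and SDC3, PLPP3, MAP1B and MRPS27, CCNH and TMEM161B, MLN and GRM4, and in SEMA6D. Of the less accessible regions 2 of 234 (0.855%) had such a neighbour, near the 0.953% that placements gave (permutation p = 0.68).

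Chromosome 3 held 31 of the 234 less accessible regions (13.2%, 9.18 to 18.3) and 150 of the 2072 more accessible ones (7.24%, 6.16 to 8.44). The odds ratio was 1.96 (1.25 to 2.98, Fisher's exact test, two-sided, p = 0.0028), and the adjusted p over 24 chromosomes was 0.068, so that 0 chromosomes passed, with 4 at an unadjusted p under 0.05. Against its length share of 6.80%, chromosome 3 was over-represented among less accessible regions (exact binomial test, adjusted p = 0.006). The X chromosome held 28 more accessible regions (1.35%) and 3 less accessible ones (1.28%) against a length share of 5.25% (exact adjusted p = 4.6e-19 and 0.024). More accessible regions exceeded the length share on chromosomes 1 and 5 (9.80% against 7.89% and 7.87% against 6.14%, exact adjusted p = 0.016 each), and for chromosome 1 the adjusted p was 0.23 with regions within 50 kb counted as 1 locus. Y held 1 more accessible region (0.0483% against 0.863%, exact adjusted p = 1.4e-05). How much of Y reads can be mapped to was not assessed, so its length share may be too high a background. The comparisons with length were added after the data had been seen.

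**Figure D4:**
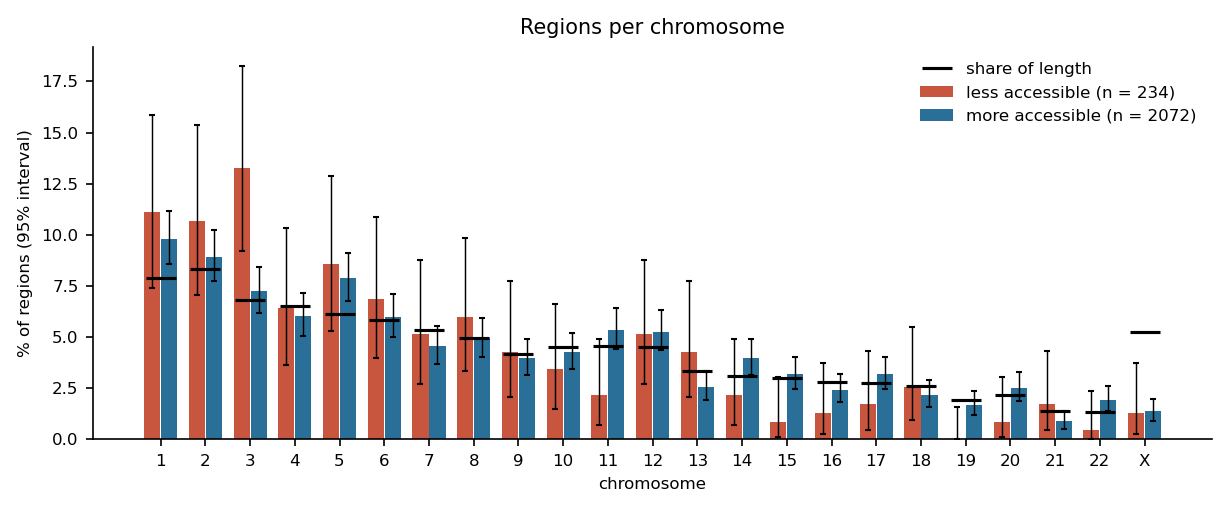
Percent of less (red, n = 234) and more accessible regions (blue, n = 2072) on each autosome and on X, with 95% exact binomial intervals, and each chromosome's share of the length as black dashes. Chromosome 3 holds 13.2% of the less accessible regions, and X holds 1.28% and 1.35% where its length share is 5.25%.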

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

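Of 71 alternative values over 25 results, 44 stayed on the same side of the threshold, or within 1.5 times for a count, without turning direction, although among them the median difference in gene density became 0 with a window of 100 kb (p = 1, permutation test). Another 13 were folds that lost the threshold, of the trophoblast and Wnt lists and, with 1 region per locus, of JARID2 and DNMT3B within their lists. The alternatives on gene density, single genes, chromosome length, autosomes for the gene lists, gene ends for the gene lists, the leading gene, the position inside genes, and the 10 kb and 250 kb distances between opposite regions were chosen after seeing the data. The difference in the share near gene ends turned to -0.37 points with a 2.5 kb window (Fisher's exact test, p = 1), and that in median distance to 1.08 kb with the ends of all annotated genes (p = 0.61); neither difference passed the threshold in any setting run. Less accessible regions near a more accessible one numbered 5 within 10 kb and 69 within 250 kb, above the 3.43 and 67.6 of random placements, where 14 within 50 kb lay below, with no p under 0.29. The median difference in gene density was -2 genes with a window of 1 Mb (permutation p = 0.035) and -2 for regions outside genes (p = 0.0037), which brought it past the threshold. The number of gene lists called in the more accessible regions was 2 as tested. It became 5 with the background matched on distance class and 5 on autosomes alone (adding pluripotency, neural ectoderm and retinoic acid with Hedgehog), 1 with nearest genes within 100 kb (neural ectoderm), 2 with every gene within 50 kb (Wnt and neural ectoderm, the latter 3.13-fold with an exact adjusted p of 0.00082, in place of the trophoblast list), and 0 with each gene counted once together with 1 region per locus, 0 with gene ends in place of gene bodies and 0 without each list's leading gene, an alternative that lowers every count by construction. In the less accessible regions it was 0 as tested, 1 with the matched background and 1 on autosomes alone (neural crest in both). The cause was not tested, but 5 lists of more accessible regions had an adjusted p between 0.048 and 0.061, so small shifts move the count. The comparison of gene lists between directions called 0 in its 5 alternatives (smallest adjusted p from 0.36 to 0.75). No paired analysis was possible because the lists carry no value per library, and for the same reason leaving out each replicate and a stricter threshold by score were not run. The planned motif and GC alternatives were not run without a genome sequence, and region width, equal in every region, had no alternative that gives a value.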

Other observations

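Among the tests below, those of the X chromosome, of copies of chromosome 3 and of chromosome 3 without its densest stretch were chosen only after the result was seen, as were the genes and groups named in the next 2 paragraphs.

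The 8 less accessible regions within 1 kb of a protein-coding gene end lay at CRIPTO, ESRP1, CLDN7, KDF1, PROM2, INSL5, ARMC9 and RIT2. ESRP1 is an epithelial splicing regulator, and its region overlapped the gene's start coordinate (chromosome 8, 94640689 to 94641188). KDF1 acts in keratinocyte differentiation, and its region overlapped the gene's end coordinate (chromosome 1, 26960172 to 26960671). PROM2 is a prominin of epithelial membrane protrusions, with a region over its start coordinate (chromosome 2, 95274247 to 95274746). No list of epithelial genes of this kind had been fixed, so no enrichment was tested.

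The long non-coding RNA genes with the most more accessible regions inside them, 3 each, were MEG3, which is imprinted (chromosome 14, between 100830605 and 100840599), NEPRO-AS1, PAPPA-AS2, LOC107987108 and LOC124904185, with no test against an expected number. The share inside any annotated long non-coding RNA was 17.1% for less and 18.2% for more accessible regions (Fisher's exact test, p = 0.72). FIGNL2 and LASP1, each nearest to 3 more accessible regions, had the lowest single-gene p-values (8.5e-06 and 1.4e-05, adjusted 0.14 for both). Grouping genes by the letters that open their symbols, over 698 tests, symbols beginning with TCF were nearest to 10 more accessible regions against 2.11 expected (4.74-fold, exact adjusted p = 0.028). These were TCF4 with 4, TCF7L2 with 2, and TCF12, TCF20, TCF21 and TCF7L1 with 1 each, which are transcription factors of different families that share the name. Genes known by a LOC identifier were nearest to 35 against 64.3 expected (0.545-fold, exact adjusted p = 0.028, and 0.18 with 1 region per locus).

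More accessible regions lay closer together than random placement gives. Sites listed as several regions within 5 kb of each other do not account for this. After such regions were merged, 11.07% of 2050 still had a neighbour within 50 kb, against 6.51% on average and 8.73% at most in placements (permutation p = 0.001, the smallest they can give). Broader sites split into several regions were not tested. Gene density within 500 kb and gene bodies do not account for the closeness either, since placements matched on both and on chromosome gave 7.62% on average and 10.5% at most against 12.8%. Gene density at a finer scale was not matched. Whether the closeness belongs to opening regions alone stays open, because draws of 234 more accessible regions gave 1.646% on average (0 to 4.27), a range that holds the 0.855% of the less accessible list. A candidate explanation that was not tested is that accessible chromatin as a whole lies in groups, and the hypothesis that neighbouring regions opened together was not tested either.

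The X chromosome held 1.35% of more accessible regions (0.900 to 1.95). A lower number of genes does not account for it, since X carries 4.232% of protein-coding genes (exact binomial test, p = 9.4e-14). H1 carries a single X, and in proportion to copy number this would give 2.706%, above the interval (exact p = 4.4e-05). Lower read depth on a single copy could remove more regions than that at the authors' threshold, which cannot be told apart from fewer changes on X without values per library. No biological explanation was tested.

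The excess of less accessible regions on chromosome 3 may have several sources. With its densest 20 Mb (9 of the 31 regions, between 175.5 and 195.3 Mb) left out, chromosome 3 still held 9.778% of less accessible regions (6.23 to 14.4). The length share without that stretch was 6.15% (exact binomial test, p = 0.035). Chromosome 3 was picked among the chromosomes for its excess, and this p is unadjusted. The narrow margin therefore cannot exclude a single segment of 20 Mb as the whole cause. Longer segments were not tested. Whether the densest 20 Mb adds to the excess stays open. Its 9 regions exceeded the 7.24 of random placements with a permutation p = 0.13, and a p above the threshold, set beforehand as the sign of no segment, excludes none. More copies of chromosome 3 before competence loss would deplete it among more accessible regions, and its share there, 7.239% (6.16 to 8.44), has an interval that holds the length share of 6.80% and does not decide. With gene density as strata the odds ratio was 1.856 (1.16 to 2.72) against 1.96 without, so gene density moved it little, but the interval is too wide to exclude a part.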
